A study of Caenorhabditis elegans with 16 samples.

How the data were processed

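Messenger RNA was measured by sequencing in whole Caenorhabditis elegans animals of 2 genotypes, wild-type N2 and the deletion mutant atf-4(ok576), with 4 biological replicates in each of 4 groups. Per the labels' protocols, synchronized larvae were raised at 20 °C on Escherichia coli OP50 to young adulthood and then kept for 24 hours at 25 °C either on OP50 (uninfected) or on Salmonella enterica SL1344 (infected). Infected and uninfected animals therefore also differ in the bacterium they fed on. A stranded mRNA kit was used, per the labels' protocols, and all 16 libraries carry the same batch label.

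Per the submitters' processing notes, bcl2fastq, HISAT2 2.2.1, featureCounts and DESeq2 1.31.16 were used with genome build ce10. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The authors deposited 2 tables, for uninfected and for infected animals, each comparing the genotypes over 8 libraries. Per the file headers and the values, each per-library column the authors deposited holds a signal, the reads of a gene divided by the size factor of that library, and each table was scaled on its own. Per the file headers, the authors also deposited a mean level, a log2 fold change with its error on the log2 scale, a test score, a p-value and an adjusted p-value for each gene. The table columns were matched to the samples by genotype, infection state and replicate number. The atf-4 gene carries its older name atf-5 in the files.

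The values of each library were whole multiples of 1 step, and the reads were recovered by dividing by that step. In every library 100% of the values came out whole within 1e-06 of a read. The recovered totals were 3.54e+07 to 5.59e+07 reads per library and the size factors ran from 0.829 to 1.26. The smallest chi-square per degree of freedom between replicates of a group was 6.16, so no library was taken to be deposited more than once. Intervals on reads cover counting error only.

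Of 42048 features in each table, those with a value of at least 10 in at least 4 of the 8 libraries were tested, 13191 in the uninfected and 13293 in the infected table. The main test was limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 on log2(value + 1), with genotype as the sole term, Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale, which understates changes of low genes. The difference of the genotype effects between infected and uninfected animals was tested in a limma fit of all 16 libraries over the 12998 genes tested in both tables. Since the tables were scaled separately, the effect of infection within a genotype was tested as a supplementary comparison with edgeR 4.0.16 quasi-likelihood on the recovered reads, with TMM factors over 16 libraries. Its levels are given as CPM, the reads of a gene scaled to the depth of the library.

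The 32 gene lists, the tests, the first set of alternatives and the rule for the named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over lists. Some genes belong to several lists, so the list tests are not independent. List tests on the difference of effects and on the infection comparisons were added after the data were seen. Gene classes (the letters before the hyphen of a name) with at least 10 tested members were tested with Fisher's exact test, two-sided, against tested genes with a class name. Of 13486 genes tested in either table, 6792 had a class name in the files. A further 1439 of the other 6694 were given a class name through locus tags of the WBcel235 reference, which was used for names, exon lengths and gene neighbours and not for coordinates.

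The named genes are atf-4 itself, and in each genotype comparison up to 10 with the largest rise and up to 10 with the largest fall. These had to pass the threshold, have a class name and a mean of at least 50 in the higher group, and show no overlap between the libraries of the groups. The infection comparisons took up to 5 in each direction by the same rule, with the mean taken in recovered reads. Up to 3 members of each list and of each enriched class were taken by adjusted p, and of these the ones that missed the threshold are not named.

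Whether the replicate numbers pair the samples was decided by a rule set in advance, that every pair of same-numbered samples correlates above 0.1 in its deviations from the group means. Counts with a replicate block had been computed by then. In the uninfected comparison the correlations were 0.55, 0.24, 0.22 and 0.38 for replicates 1 to 4, so there the numbers were taken to pair the samples, on the evidence of the data alone. That evidence was weak, since libraries with numbers 2, 3 and 4 correlated more closely with one of another number (0.40, 0.36 and 0.50). In the other comparisons at least 1 pair was under the limit.

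The steps were tested on simulated reads. At a 2-fold change limma recovered 71.6% of the changed genes in the simulated uninfected comparison over 13191 genes, 80.6% in the infected comparison over 13293 genes and 53.7% for the difference of effects over 12998 genes. At 1.5-fold these shares were 14.9%, 47.8% and 25.4%. In the simulated infection comparisons edgeR recovered 71.6% of 2-fold changes in wild type over 13369 genes and 83.6% in atf-4 over 13127 genes. Unchanged genes called were 8, 13 and 6 in the simulated uninfected, infected and difference comparisons, and 11 and 9 for infection in wild type and atf-4. Genes were simulated independently, without any structure shared between libraries, so these shares may not hold for the real libraries.

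Alternatives fixed before the data were examined were TMM factors, quantile normalization, pseudocounts of 0.5 and 8, no filter, a filter at 50, edgeR and DESeq2 1.42.0 on the recovered reads, a replicate block, all 16 libraries in one fit, a 2-fold threshold, an adjusted threshold of 0.01 for the overlap, and leaving out each library. Alternatives added after the data were seen were 1 surrogate variable (sva 3.50.0), leaving out together the pair of libraries farthest along the first principal component, the replicate block for the overlap, and leaving out each library for the list and overlap counts. Genes without a class name were counted and, with the exceptions stated where they appear, not named.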

Results

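RNA was sequenced from whole adult C. elegans of the wild-type strain N2 and of atf-4(ok576). The latter is a deletion mutant of the stress-responsive bZIP transcription factor ATF-4. Animals had been raised to young adulthood and had then spent 24 hours on E. coli OP50 (uninfected) or on the pathogen S. enterica SL1344 (infected). Each of the 4 groups held 4 biological replicates. The recovered depth was 3.54e+07 to 5.59e+07 reads per library, and 17155 to 18220 features had at least 1 read. Yolk protein (vitellogenin) genes took up to 17.7% of the reads of a library.

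The targeted gene, listed as atf-5, was examined first. In uninfected animals its normalized read count was 1891 ± 350.1 in wild type and 2.02 ± 1.1 in atf-4 mutants (SD, n = 4 each). In infected animals it was 1528 ± 131 and 1.58 ± 1.02. Each mutant library held 1 to 4 reads of the gene, against 1345 to 2232 in uninfected and 1369 to 2030 in infected wild-type libraries. From the pooled reads, scaled to depth, wild type exceeded the mutant 881-fold without infection (95% counting interval 464 to 1926) and 963-fold with it (442 to 2625). All 16 libraries thus matched their genotype labels.

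The first comparison asked which transcripts differed in atf-4 mutants without a pathogen. Besides atf-5, the named genes that fell were math-26, of the MATH domain family, haf-6, which encodes an ABC transporter, and tag-257. The level of math-26 was 284 ± 60.7 in wild type and 4.27 ± 1.88 in the mutant (SD, n = 4 each), a log2 fold change of -5.82 ± 0.31 (SE, limma adjusted p = 2.3e-05). The level of haf-6 was 1907 ± 311 against 744 ± 72.1 (log2 fold change -1.35, adjusted p = 0.0028), and that of tag-257 536 ± 25.9 against 314 ± 13.8. Of the genes that rose, clc-19, listed as T24C4.4 and named for a claudin-like protein, went from 97.1 ± 15.8 to 281 ± 31.8. The gene chca-1, listed as F58G6.9, went from 221 ± 18.5 to 519 ± 72.8, and cpr-3, a cathepsin B-like cysteine protease gene, from 567 ± 70.5 to 969.8 ± 59.6 (adjusted p = 0.039).

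In total 13 of 13191 genes passed the threshold in uninfected animals in the fit without pairing, 6 higher and 7 lower in the mutant. With the replicate number as a block, the pairing that the preset rule chose, the count was 138, of which 74 were higher and 64 lower. At least 2-fold changes were 10 without pairing and 62 with it, the latter 21 higher and 41 lower. The genes named above were selected without pairing, and all 7, atf-5 included, kept their calls with the block. Without wild-type replicate 4, and without pairing, the count was 44, of which 11 were higher and 33 lower. The recovered reads gave 13 genes with edgeR and 77 with DESeq2, and the authors' deposited table holds 84 genes at an adjusted p under 0.05, 44 higher and 40 lower. The call for cpr-3 was lost in 7 of the 8 fits that left out 1 library, with wild-type replicate 3 as the exception, and that for tag-257 in 4, those without wild-type replicate 3 or atf-4 replicate 2, 3 or 4. Without both atf-4 libraries 3 and 4 the calls for cpr-3, tag-257, clc-19 and chca-1 were lost (adjusted p = 0.40, 0.097, 0.055 and 0.059).

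Among the fixed lists in uninfected animals, camera with its preset correlation placed 4 higher and 6 lower in the mutant, while math-26 was their sole member past the threshold over all genes. Of 41 tested embryo markers, zygotic genes of embryos held in utero, 35 had a positive log2 fold change, with a median of 0.49 (adjusted p = 3.0e-11). F-box and MATH or BTB family genes were positive in 203 of 279, although math-26 fell. Nuclear hormone receptors had a median of 0.11 over 177 genes, and the intracellular pathogen response list 0.20 over 19. Lower were oocyte and germline markers (1 of 24 positive, median -0.19), ribosomal proteins (median -0.14 over 76), heat shock proteins (-0.11 over 19), molting-cycle genes (-0.06 over 82), cuticle collagens (-0.10 over 106) and insulin pathway outputs (-0.13 over 18). With an estimated correlation each of these 10 lists had an adjusted p = 0.90, and fry gave at least 0.65. Libraries also differed within the genotypes: on the first principal component atf-4 replicates 3 and 4 lay at 37.9 and 36.1, and ribosomal levels were higher in replicates 1 and 2 than in 3 and 4 in both genotypes. Of the 35 splits of the libraries 18 gave at least as many lists. Counted within each list, adjusted over the list alone, 2 heat shock genes and 2 collagens were lower, and 1 F-box, MATH or BTB gene was higher and 1 lower. The number of lists was 4 without wild-type replicate 1, and 5 and 6 without atf-4 replicates 3 and 4.

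By the preset camera, 4 list calls in uninfected animals held without any 1 library. They were embryo markers, oocyte and germline markers, nuclear hormone receptors and F-box, MATH and BTB genes. None of them passed with an estimated correlation or by fry. That for ribosomal proteins was lost without wild-type replicates 1 and 2 (adjusted p = 0.33 and 0.94) and without atf-4 replicates 3 and 4 (0.44 and 0.71), and that for collagens without wild-type replicates 1 and 2 (0.47 and 0.60) and atf-4 replicate 3 (0.19). The intracellular pathogen response lost its call without wild-type replicates 1 and 2 (0.14 and 0.27) and atf-4 replicates 3 and 4 (0.28 and 0.11), and insulin outputs without wild-type replicates 1 and 3 (0.47 and 0.052) and atf-4 replicates 3 and 4 (0.33 and 0.17). Heat shock genes lost it without wild-type replicate 1 (0.054) and atf-4 replicate 4 (0.10), and molting-cycle genes without wild-type replicates 1 and 3 (0.054 and 0.13) and atf-4 replicate 3 (0.11).

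The second comparison asked which transcripts differed in atf-4 mutants during infection. Among genes that met the naming rule, which leaves out genes without a class name, the largest rises included neuropeptide genes. The level of nlp-20 went from 136 ± 24.8 in wild type to 364 ± 54.6 in the mutant (SD, n = 4 each; log2 fold change 1.42 ± 0.16 SE, limma adjusted p = 0.0019), and flp-15, nlp-10 and nlp-17 rose by 1.16, 0.87 and 0.86 on the log2 scale. The acid phosphatase gene pho-11 rose from 2284 ± 223 to 4751 ± 542 (log2 fold change 1.05, adjusted p = 4.9e-04), the aspartyl protease gene asp-8 by 1.04 on the log2 scale (adjusted p = 0.018), and the acid sphingomyelinase gene asm-3 from 66.0 ± 5.94 to 125 ± 39.5. The spinster homolog spin-3 rose from 45.3 ± 7.51 to 117 ± 15.8, the acyl-CoA dehydrogenase gene acdh-2 from 217 ± 46.1 to 402 ± 31.7, and spig-20, listed as C45B2.1, from 211 ± 55.2 to 446 ± 109.

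Besides atf-5, the largest fall in infected mutants among genes that met the naming rule was that of math-26, from 315 ± 83.9 to 3.53 ± 2.37 (log2 fold change -6.25 ± 0.37 SE, adjusted p = 1.6e-05). The others among the largest of these were genes of the cuticle and the molting cycle: the collagens col-168, col-167, col-125 and col-130, the ground-like genes grl-16 and grl-5, the cuticlin gene cut-2, and abu-14. Their log2 fold changes ran from -3.19 for col-168 (adjusted p = 0.036) to -2.40 for cut-2 (adjusted p = 0.031). Genes without a class name fell by as much, such as F08D12.2 (-3.32) and C27D8.2 (-3.01), so the ranking does not show that cuticle genes made up all of the largest falls. These genes varied widely among infected wild-type libraries. The values of col-168 were 289, 161, 62.0 and 12 in wild-type replicates 1 to 4, with a mutant mean of 7.96 ± 2.73. Those of grl-16 were 803, 459, 128 and 83.8, with a mutant mean of 40.4 ± 5.61. All of these cuticle and molting genes lost their calls without atf-4 replicate 2 and without atf-4 replicate 3, and all but abu-14 without wild-type replicate 1.

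In infected animals 831 of 13293 genes passed the threshold, 493 higher and 338 lower, and 77 of them changed at least 2-fold, 12 higher and 65 lower. The authors' deposited table holds 1705 genes at an adjusted p under 0.05, 866 higher and 839 lower. With quantile normalization 766 genes passed, of which 374 were higher. Without both wild-type replicates 1 and 2 the count was 552, with 199 higher and 353 lower, so the excess of higher genes depended on the scaling and on the libraries. The count was 270, 519 and 265 without wild-type replicates 1, 2 and 3, and 438, 112 and 122 without atf-4 replicates 1, 2 and 3. It was 27 when all 16 libraries shared one estimate of the spread and 1659 with DESeq2 on the recovered reads. In this comparison 86 genes were selected by the naming rule, not all of them printed here. Of these, 5 kept their call under every alternative in which they were counted (atf-5, math-26, nlp-20, spin-3 and acdh-2). Genes changed less than 2-fold, acdh-2 among them, were not counted under the 2-fold threshold, which they miss. The call was lost for 78 of 85 with all 16 libraries in one fit, 53 without atf-4 replicate 2 and 49 without atf-4 replicate 3.

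Ribosomal protein genes formed a large group of small rises in infected mutants. Of 76 tested, 54 were higher and 0 lower past the threshold, 72 higher when adjusted over the list alone, with a median log2 fold change of 0.28. Examples are rps-16 (32724 ± 1670.2 against 42539 ± 2186; log2 fold change 0.38, adjusted p = 0.0084), rps-13 (0.37) and rpl-32 (0.34). With quantile normalization the median was 0.077 and 14 members passed. Random gene lists matched on exon length and level had a median of 0.24. Camera gave an adjusted p = 2.5e-36 with the preset and an adjusted p = 0.44 with an estimated correlation.

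Several lists of defence genes were higher in infected mutants by the preset test, though not the intracellular pathogen response (9 of 20 positive, median -0.04, adjusted p = 0.45). None of these calls held with an estimated correlation (adjusted p = 0.46 for antimicrobial peptides, lectins, infection response genes and lysozymes, and 0.56 for the PMK-1 list). Intestine markers were higher by the preset test as well (10 of 11 positive, median 0.23; adjusted p = 0.46 with an estimated correlation), and whether the defence genes moved apart from them was not tested. Of 46 antimicrobial peptide genes 9 were higher and 0 lower, 14 higher when adjusted over the list alone, among them the saposin-like spp-3 (6002 ± 373 against 8233 ± 412; log2 fold change 0.46) and spp-17 (0.35), and nlp-34 (0.84). Of 87 C-type lectin genes 8 were higher and 1 lower, 10 and 1 when adjusted over the list alone; clec-5 rose from 1622 ± 172 to 2759 ± 53.7, clec-48 by 0.78 and clec-50 by 0.34 on the log2 scale. Of 22 infection response genes 6 were higher, 9 when adjusted over the list alone, including irg-5, listed as F35E12.5 (81.9 ± 14.3 against 146 ± 21.1), the immune bZIP factor gene zip-2 (0.32) and dod-19 (0.35). Of 12 lysozyme genes lys-1 and lys-2 were higher (0.32 and 0.29), 3 when adjusted over the list alone.

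The PMK-1 p38 pathway list was positive in 8 of 14 genes in infected mutants. In it irg-5, clec-85 and the phosphatase gene vhp-1 were higher (log2 fold changes of 0.83, 0.29 and 0.42), with 5 higher and 1 lower when adjusted over the list alone. The gene irg-5 also counts among the infection response genes and clec-85 among the C-type lectins, so these lists are not separate results. The camera adjusted p with the preset correlation was 3.4e-05 for antimicrobial peptides, 0.0044 for lectins, 0.014 for infection response genes, 0.045 for lysozymes and 0.046 for the PMK-1 list. As given above, none of these lists passed with an estimated correlation. Lysozymes, infection response genes and the PMK-1 list missed the threshold without wild-type replicate 3 (adjusted p = 0.13, 0.12 and 0.20), and lysozymes and the PMK-1 list also without atf-4 replicate 1 (0.10 and 0.086) or 2 (0.062 and 0.054). Lysozymes missed it without wild-type replicate 4 as well (0.094), and the PMK-1 list without wild-type replicate 2 (0.063).

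Other lists were also higher in infected mutants by the preset test. With an estimated correlation the adjusted p was 0.56 for neuropeptides, 0.46 for vitellogenins, intestine markers and insulin outputs, 0.44 for oxidative stress genes and 0.37 for heat shock genes. Of 103 neuropeptide genes 8 were higher, 11 when adjusted over the list alone, with nlp-40 as a further example (log2 fold change 0.29). All 6 vitellogenins were positive, with a median of 0.24; 0 passed over all genes, and 6 did when adjusted over the list alone. Of 32 oxidative stress genes 4 were higher, 9 when adjusted over the list alone, among them the peroxiredoxin gene prdx-2 (0.29) and the superoxide dismutase genes sod-1 (0.24) and sod-2 (0.24). Of 11 intestine markers 10 were positive (median 0.23); 4 were higher, 5 when adjusted over the list alone, including act-5, vha-6 and asp-3 (0.33, 0.31 and 0.32). The small heat shock gene hsp-25 (0.49) was the sole higher member of 19 heat shock genes, 4 when adjusted over the list alone, and lea-1 (0.35) of 18 insulin pathway outputs, 3 when adjusted over the list alone.

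For these lists in infected mutants the preset camera gave adjusted p = 3.4e-05 for neuropeptides, 0.0021 for vitellogenins, 0.0023 for intestine markers, 0.0044 for heat shock genes, 0.011 for oxidative stress genes and 0.045 for insulin outputs. None of these calls held with an estimated correlation. By fry the ribosomal, heat shock, vitellogenin, oxidative stress and antimicrobial lists moved up, with adjusted p = 0.018, 0.018, 0.026, 0.028 and 0.033. Insulin outputs missed the camera threshold without wild-type replicate 2 or 3 (adjusted p = 0.063 and 0.15) and without atf-4 replicate 1 or 2 (0.10 and 0.060). Leaving out wild-type replicate 3 lowered the number of lists past the threshold from 14 to 9.

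The molting-cycle list was lower in infected mutants by the preset test (adjusted p = 0.0055; adjusted p = 0.63 with an estimated correlation), with 8 of 84 members lower and 2 higher; ptr-21 (0.30) and nas-9 (0.50) were the higher ones. Adjusted over the list alone, 10 were lower and 3 higher. The mean level of this list stood 0.61 and 0.43 above the gene means of the table on the log2 scale in infected wild-type replicates 1 and 2, against -0.14 and -0.06 in replicates 3 and 4 and -0.28 to -0.09 in the mutant. F-box and MATH or BTB genes were lower as a list (median -0.11 over 285; adjusted p = 0.045, and adjusted p = 0.60 with an estimated correlation). Of these, fbxa-125 (2.68) and math-26 alone passed, in opposite directions, and the counts adjusted over the list alone were the same. The list call was lost without wild-type replicate 2 or 3 (adjusted p = 0.23 and 0.18) and without atf-4 replicate 3 or 4 (0.087 and 0.086).

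Cuticle collagens split in infected mutants. Of 107 tested, 19 were higher and 7 lower, 29 and 42 when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.59, with a median of -0.24 and a mean of -0.74, while fry placed it on the higher side with adjusted p = 0.92). The higher ones included col-143, which went from 24041 ± 2235 to 37221 ± 3477 (log2 fold change 0.63), col-106 (0.59) and col-122 (0.53). By Fisher's exact test on gene classes, higher genes were enriched for rpl (32 of 45), rps (22 of 31), col (19 of 89; adjusted p = 8.1e-07), lec (7 of 12; adjusted p = 1.5e-05), nspg (5 of 10), asp (5 of 12), spp (6 of 19), cox (4 of 11) and vha (5 of 20; adjusted p = 0.047). The galectin genes lec-8, lec-9 and lec-10 rose by 0.38, 0.36 and 0.54 on the log2 scale, and the aspartyl protease genes asp-2 and asp-4 by 0.46 and 0.29. Genes for subunits of cytochrome c oxidase (cox-6B by 0.34) and of the vacuolar proton pump (vha-3 by 0.34) rose by similar amounts. Over 12797 tested genes with a known exon length, log2 fold changes in infected animals fell with length (Spearman's rho -0.22). The class tests, and the list tests above, did not account for length, so small rises of short genes may partly follow this trend. No class passed among lower genes in infected animals, or in either direction in uninfected ones.

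In lists that did not pass in infected animals, single members did. The S-adenosylhomocysteine hydrolase gene ahcy-1 was higher (0.25) among 31 amino acid and one-carbon metabolism genes, and the mitochondrial protease genes ymel-1 and spg-7 and the chaperone gene dnj-10 were lower (-0.25, -0.25 and -0.41) among 17 genes of the mitochondrial unfolded protein response. The autophagy genes atg-4.2 and epg-8 were lower (-0.43 and -0.32) among 26. In lipid metabolism 7 of 83 genes were higher and 0 lower, among them acdh-2, ech-7 (0.66) and lipl-5 (0.35). Adjusted over the list alone, the counts higher and lower were 3 and 1 for the amino acid list, 2 and 7 for the mitochondrial list, 0 and 2 for autophagy, and 9 and 1 for lipid metabolism. Of the 21 cytosolic tRNA synthetase genes, a group of ATF4 targets in mammals, 0 were higher and 0 lower in limma in either state, and as many when adjusted over the list alone (camera adjusted p = 0.26 and 0.29).

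**Figure D1:**
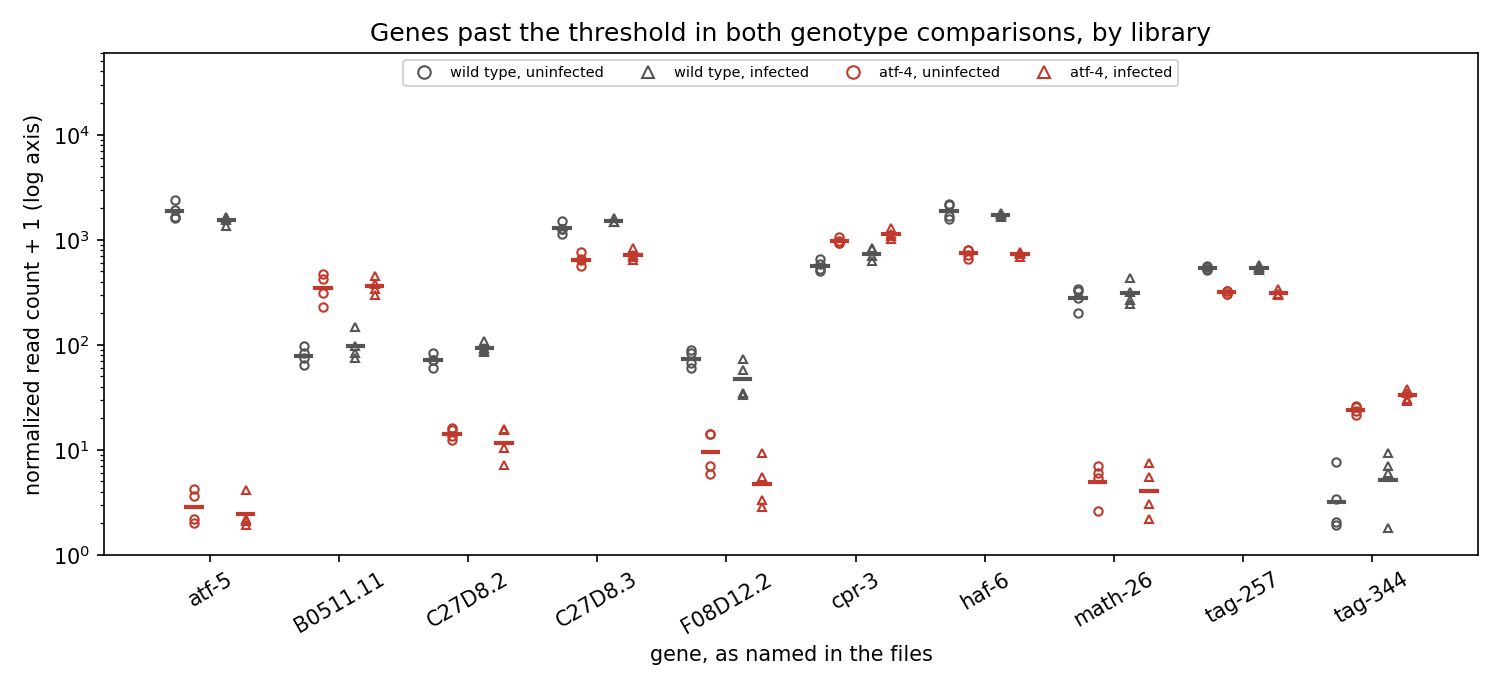
Normalized read count plus 1 on a log axis for each library (symbols) with the mean of the log values (bars), for the 10 genes past the threshold in both genotype comparisons. The mutant and wild-type libraries of each gene lie apart with and without infection; atf-5 is the targeted gene.

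The overlap of the genotype comparisons asked how far mutant differences were the same with and without infection. The genes lower in both were atf-5, math-26, haf-6 and tag-257, and cpr-3 was higher in both. A further 5, outside the naming rule and chosen after their values were seen, were C27D8.2, C27D8.3 and F08D12.2, which were lower, and B0511.11 and tag-344, which were higher. The log2 fold changes without and with infection were -1.35 and -1.24 for haf-6, -2.33 and -3.01 for C27D8.2, and 2.13 and 1.91 for B0511.11. Of 12998 genes tested in both, 7 were lower in both against 0.179 for independent lists (Fisher's exact test, p = 6.7e-12), and 3 were higher in both against 0.227 (p = 9.9e-04). The 7 include the targeted gene atf-5, whose fall in both states follows from the genotype, and the test was not run without it. The total of 10 became 20 without uninfected wild-type replicate 4, and 6 without uninfected atf-4 replicate 2 or 3. It rests on fits without pairing, and was 35 with the replicate block in the uninfected comparison alone, where the numbers were taken to pair the samples. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.31 (0.27 without atf-5) and Spearman's rho -0.21.

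**Figure D2:**
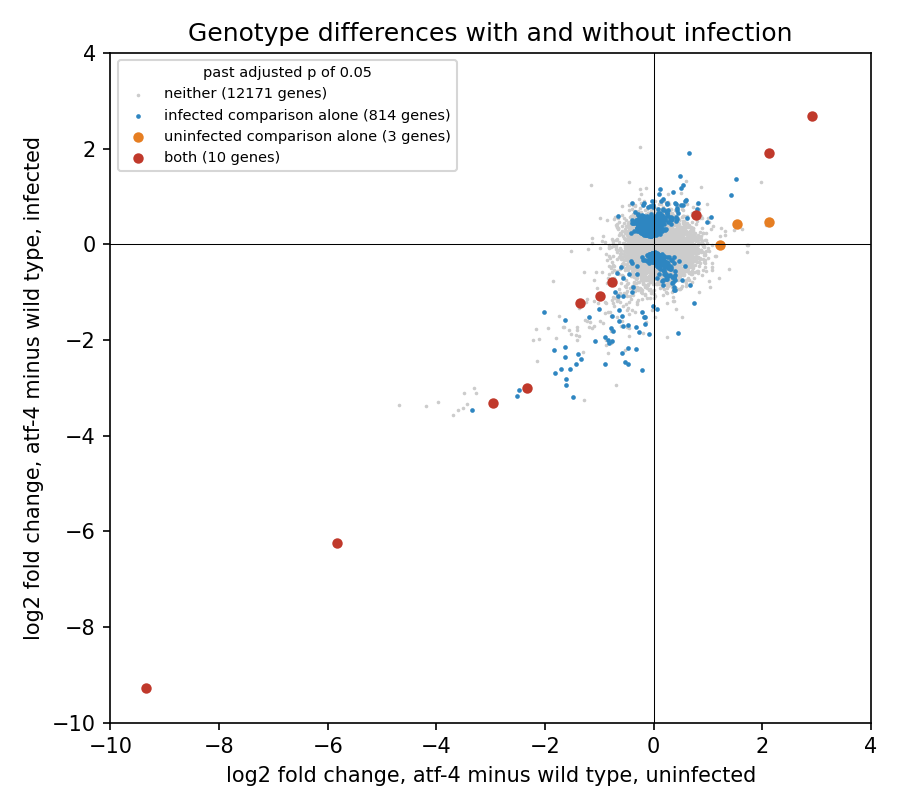
Log2 fold change of atf-4 over wild type in uninfected (x axis) and infected (y axis) animals for 12998 genes, coloured by the comparison in which they passed. The 10 genes past the threshold in both have the same sign in both.

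The difference of the genotype effects between infected and uninfected animals was tested directly. In limma 0 genes passed, with 1168 at an unadjusted p under 0.05, and 0 passed with edgeR. The unadjusted count depended on single uninfected libraries. It was 3559, 634 and 531 without atf-4 replicates 1, 3 and 4, and 536, 1919 and 2018 without wild-type replicates 2, 3 and 4. It was also 732 without infected atf-4 replicate 3, and 2450 with the replicate block. DESeq2 on the recovered reads called 3, named after their values were seen. They were btb-21 (difference of -2.03, adjusted p = 0.015), clc-19 (-1.12, adjusted p = 0.012) and chca-1 (-1.24, adjusted p = 0.015); the limma adjusted p was 0.18 for btb-21 and 0.44 for the other pair. Genes that passed in infected animals alone are therefore not shown to differ between the states. Among lists, ribosomal proteins had the smallest adjusted p by the preset camera, 1.9e-14, with a median difference of 0.42 (adjusted p = 0.63 with an estimated correlation).

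**Figure D3:**
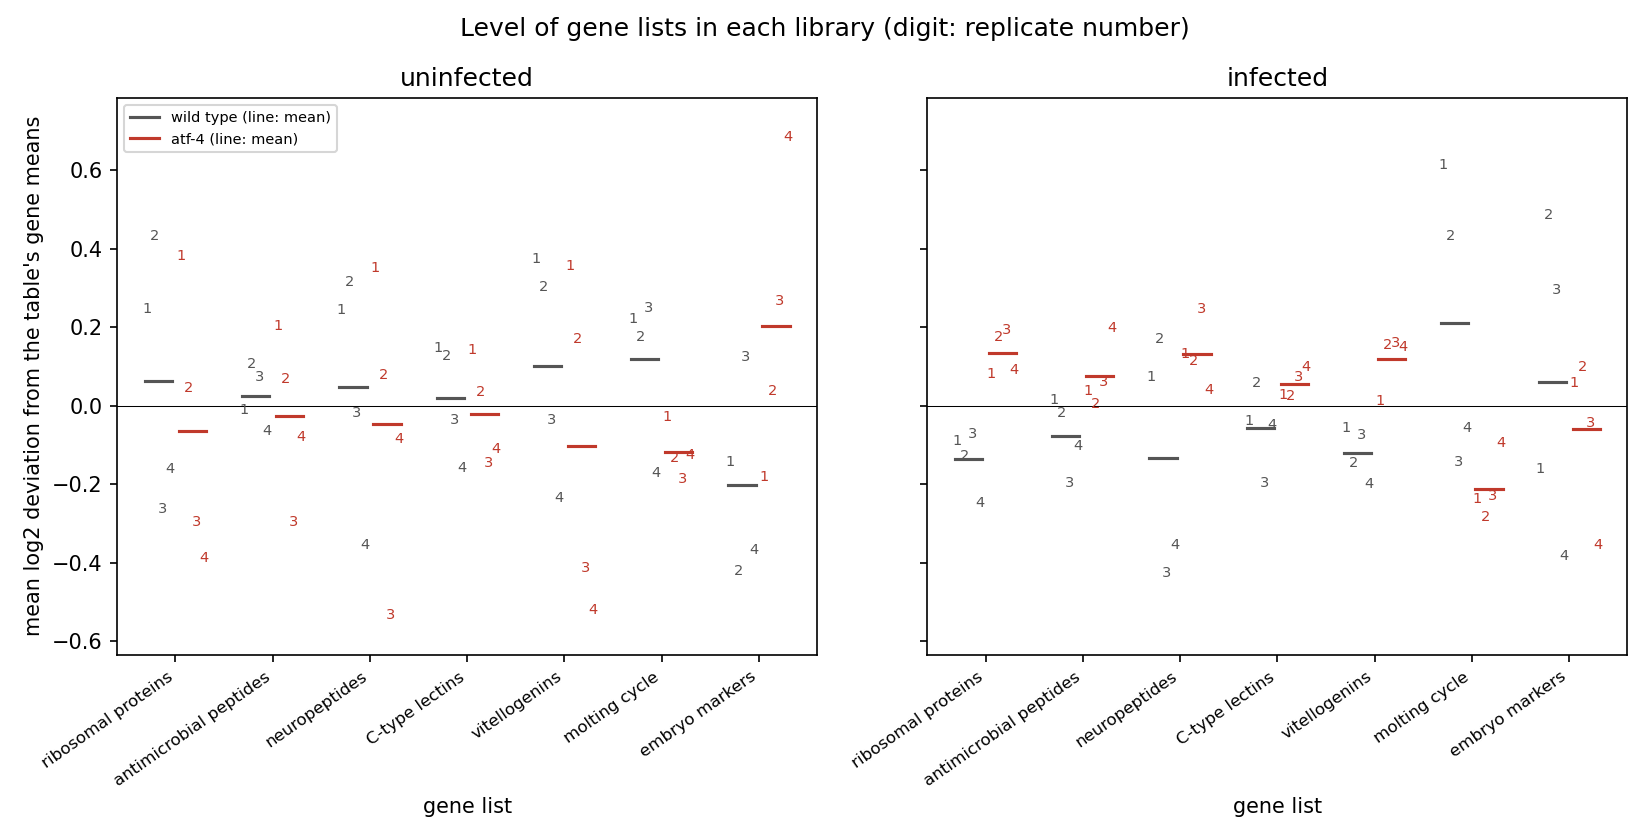
Mean log2 deviation of 7 gene lists in each library from the gene means of its table, uninfected (left) and infected (right); digits are replicate numbers and lines are group means. All infected mutant libraries lie above all infected wild-type libraries for ribosomal proteins.

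The supplementary comparison asked what 24 hours on S. enterica in place of E. coli changed within each genotype. In wild type the heme-responsive genes hrg-1 and hrg-3, the aspartyl protease gene asp-10, the carnitine palmitoyltransferase gene cpt-3 and the collagen gene col-39 had the largest rises among genes that met the naming rule. The call for col-39 was lost in 6 of the 8 fits that left out 1 library, all but those without infected replicate 3 or 4 (adjusted p up to 0.10). The level of asp-10 went from 32 to 264 CPM (means, n = 4 each; log2 fold change 3.04, edgeR adjusted p = 6.5e-06), and that of hrg-1 from 7.44 ± 0.939 to 37.2 ± 2.94 CPM. The largest falls were those of the cytochrome P450 genes cyp-35A4, cyp-35A3 and cyp-13A5, the P-glycoprotein gene pgp-1 and the lectin gene clec-210. The level of pgp-1 went from 57.7 ± 6.90 to 2.75 ± 0.387 CPM (log2 fold change -4.38, adjusted p = 5.3e-08). In total 550 of 13369 genes passed, 185 higher and 365 lower. DESeq2 gave 952.

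In atf-4 animals the largest rises with infection, by the same rule, were those of hrg-3, asp-10, pud-3, pud-4 and dct-8, and the largest falls those of cyp-35A3, pgp-1, rips-1 (listed as R08E5.3), clec-210 and cyp-13A7. The level of pud-3 went from 6.86 ± 0.855 to 57.8 ± 0.598 CPM (SD, n = 4 each; log2 fold change 3.08, edgeR adjusted p = 8.2e-08) and that of pgp-1 from 62.5 ± 4.23 to 3.62 ± 0.329 CPM. Of 13127 genes 642 passed, 256 higher and 386 lower. The count was 1002 with DESeq2, 1110 and 414 without uninfected replicates 1 and 2, and 358, 411 and 363 without infected replicates 1, 2 and 3.

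The responses of the genotypes to infection shared many genes. Of 13006 genes tested in both, 116 rose in both against 3.51 for independent lists, and 218 fell in both against 10.7, while 0 went in opposite directions. Pearson's r across genes was 0.52 and Spearman's rho 0.16. By Fisher's exact test, lower genes were enriched for cyp (13 of 54 in wild type, adjusted p = 1.8e-06, and 16 of 56 in atf-4, adjusted p = 2.3e-09) and clec (14 and 11 of 86), and higher genes for hrg (4 of 12 in each), oac and ttr. In wild type spp (6 of 19) and dhs (6 of 29) were also enriched among lower genes, and in atf-4 animals ugt (9 of 54), fbxb (10 of 94) and sdz (5 of 27). In atf-4 animals clec was enriched among higher genes too (7 of 86), with clec-67, clec-86 and clec-145 rising by 1.67, 1.47 and 0.67 on the log2 scale. The call for clec-145 was lost without uninfected replicate 2, 3 or 4 and without infected replicate 1 or 3 (adjusted p up to 0.076).

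Several defence and metabolic groups were lower with infection by the preset test, and so were intestine markers in wild type; none of these list calls held with an estimated correlation. In wild type 3 of 11 intestine markers fell, ges-1, asp-3 and act-5 (-0.58, -0.86 and -0.64 on the log2 scale), 7 when adjusted over the list alone (median -0.42, camera adjusted p = 2.8e-05; adjusted p = 0.30 with an estimated correlation). In atf-4 animals 2 fell, ges-1 and pept-1 (-0.42 and -0.80), 2 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.059). The call for act-5 was lost in 5 fits that left out 1 library (adjusted p up to 0.084), that for asp-3 without infected wild-type replicate 3 (0.051), and those for ges-1 and pept-1 in atf-4 in 6 each (up to 0.13). The lysozyme genes lys-4, lys-6 and lys-10 fell in both genotypes, among 5 of 13 lower in wild type and 5 of 12 in atf-4. Adjusted over the list alone, 8 were lower in wild type, and 7 were lower and 1 higher in atf-4. The level of lys-4 went from 271 ± 46.8 to 72.1 ± 10.2 CPM in wild type and from 229.7 ± 51.1 to 78.9 ± 7.41 CPM in atf-4. Of the PMK-1 list, clec-67, C17H12.8 and K08D8.5 rose in both genotypes (log2 fold changes of 1.63, 0.87 and 0.64 in wild type); 3 of 14 were higher and 1 lower in wild type, and 3 and 1 of 14 in atf-4. Adjusted over the list alone these counts were 4 and 1 in wild type and 5 and 1 in atf-4, where the list was higher by the preset camera (adjusted p = 0.017; adjusted p = 0.29 with an estimated correlation). The saposin-like genes spp-8 and spp-18 fell in both, and the infection response genes dod-17 and dod-22 rose in both.

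Lipid genes fell with infection in 16 of 83 in wild type and 11 of 82 in atf-4, among them acs-2 and acdh-2, and rose in 2 and 1, with cpt-3 among those that rose in wild type (log2 fold change 2.76). Adjusted over the list alone, 30 and 16 fell and 3 and 2 rose. One-carbon and amino acid genes fell in 7 and 4 of 31, 11 and 5 when adjusted over the list alone, including the S-adenosylmethionine synthetase gene sams-1 in both genotypes and ahcy-1 in wild type. The methionine sulfoxide reductase gene msra-1 fell from 103 ± 2.76 to 24.8 ± 1.55 CPM in wild type, and the nuclear receptor gene nhr-114 from 115 ± 17.9 to 29.3 ± 2.19 CPM. In the insulin output list 7 of 17 fell in wild type and 6 of 18 in atf-4, as many when adjusted over the list alone, with mtl-1, aqp-1 and ctl-2 in both. In wild type the preset camera gave adjusted p = 2.0e-06 for lysozymes, 1.0e-06 for lipid genes, 4.3e-05 for amino acid genes and 9.5e-07 for insulin outputs, and in atf-4 0.0043, 1.2e-04, 2.2e-04 and 0.0082. With an estimated correlation the adjusted p was 0.18 for all 4 in wild type, and in atf-4 0.57 for lysozymes and insulin outputs and 0.29 for the other lists.

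**Figure D4:**
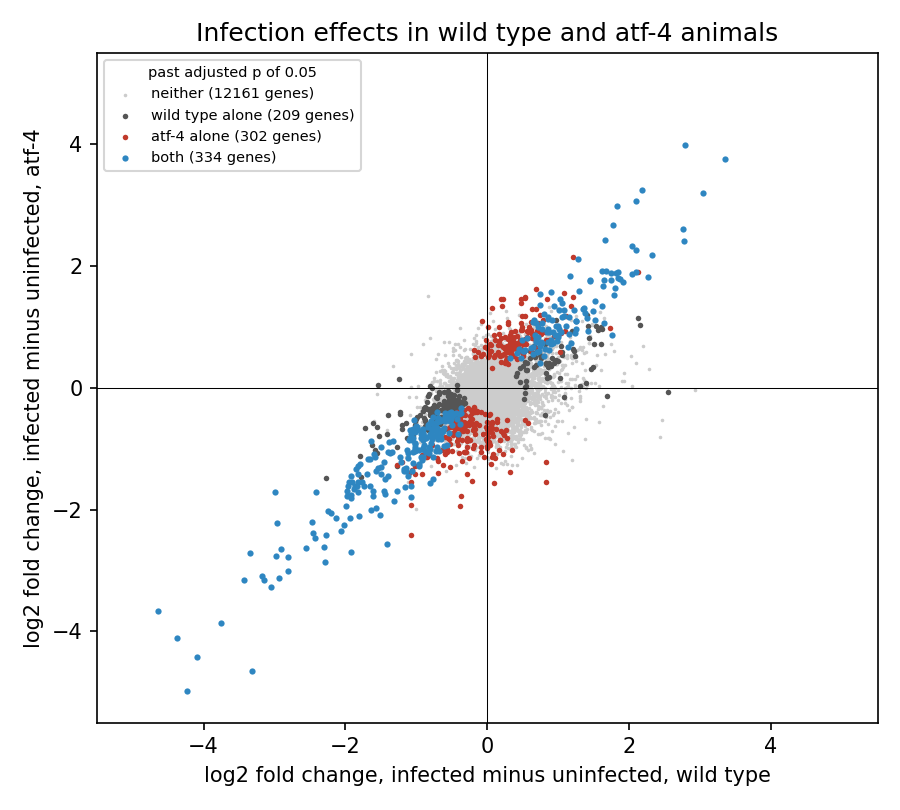
Log2 fold change with infection in wild type (x axis) and atf-4 animals (y axis) for 13006 genes, coloured by the genotype in which they passed. The 116 genes higher and 218 lower in both have the same sign in both genotypes.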

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

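Chosen only after the results were seen were the tests of a shared library axis, of scaling, of gene clusters and of younger animals, and the list tests on the difference of effects.

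Ribosomal protein genes were higher in infected atf-4 animals, with a mean log2 difference of 0.27 (SE 0.05). A library-to-library axis taken from the uninfected animals is argued against as the whole cause, since with its score as a covariate the difference was 0.218 (SE 0.042). Gene length and level stay open as a cause, since the median of the list lay at percentile 94.05 of 10000 random lists matched on exon length and level, with 74 of 76 members matched. The median was 0.28 with TMM factors, as with the authors' scaling, and fell to 0.0774 with quantile normalization. Quantile normalization gives all libraries the same distribution of values. It would therefore also shrink a true shared rise of genes as abundant as these, with mean log2 levels of 15.1 to 15.5 per infected library. That fall cannot decide about scaling, which stays open. Loss of atf-4 is a further explanation that may hold and that the design cannot separate from these.

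The genes past the threshold in both infection states had the same direction in both, with 0 in opposite directions. Selection for passing in both does not fix the direction. Of the genes past the threshold in uninfected animals, 5 of 6 higher and 7 of 7 lower ones kept their sign in infected animals. These were counted whether or not they passed there, and the 7 include atf-5. Over all genes the effects were related weakly (Pearson's r 0.31, 0.27 without atf-5, and Spearman's rho -0.21). The genes past the threshold in both numbered 10 in fits without pairing, on which the tests below rest. They numbered 35 with the replicate block in the uninfected comparison alone. Variants linked to the atf-4 deletion that act on genes of their own chromosome are argued against as the cause. The reason is that 0 of the 8 genes that were placed lay on the chromosome of atf-4. Linked variants that act on genes elsewhere were not tested. Clusters of strain variants elsewhere stay open: 2 pairs lay within 10 genes of each other, B0511.11 with tag-344 and C27D8.2 with C27D8.3, and 0.03% of 10000 random draws gave as many. Neighbours that are regulated together, or that share reads, would also give such pairs and were not tested apart. Dependence on atf-4 itself was not tested apart from the strain background.

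Molting-cycle genes were lower as a list in infected atf-4 animals by the preset test (8 of 84 members lower and 2 higher; adjusted p = 0.63 with an estimated correlation and 0.090 with a filter at 50), led by high levels in wild-type replicates 1 and 2. Younger animals in some samples would lower vitellogenins where molting genes are high. Between the infected groups the means went that way, since all 6 vitellogenins were higher in the mutant (median 0.24, fry adjusted p = 0.026, camera adjusted p = 0.46 with an estimated correlation). Age there is not separable from genotype. Within infected wild type they did not. Vitellogenins took 14.4% and 13.6% of the reads in replicates 1 and 2, where molting genes were high, against 13.9% and 13.5% in replicates 3 and 4. Over the deviations of 16 libraries from their group means, Pearson's r between molting and vitellogenin levels was 0.306 (permutation p = 0.056). Spearman's rho was 0.27 (permutation p = 0.28), and r was 0.33 without the 2 libraries farthest from the median. Within the 8 infected libraries r was 0.25. A bound that any r of 0 or above would exclude this explanation was too lax, since the r over 16 libraries had a permutation p above 0.05. The need for a p under 0.05 was added after r was seen. The explanation and an effect of atf-4 thus cannot be told apart, because r was neither below 0 nor above it at a permutation p under 0.05.

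Of the 35 splits of the 8 uninfected libraries into groups of 4, 3 gave at least the 13 genes of the real split. By this count of genes chance cannot be excluded over all splits. The highest other split, libraries 1 and 2 of both genotypes against 3 and 4, gave 4924 genes, which points to a structure of the samples. Among the 8 splits that part all 4 same-numbered pairs, the real split alone gave as many, and the highest other gave 0. With 8 splits no outcome could give a share under 0.05, so this count cannot decide about chance. The infected comparison shares no library with the uninfected one. Of the genes past the threshold in uninfected animals, 3 of 6 higher and 7 of 7 lower ones, atf-5 included, passed there in the same direction. Independent lists would share 0.227 and 0.179, so for these shared genes the overlap argues against chance. For the uninfected lists 18 of 35 splits gave as many as the real 10 (highest other 18), so chance cannot be excluded.

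Of the 35 splits of the infected libraries 1 gave at least 831 genes, the real split, and the highest other gave 2. The real split alone is the smallest share that 35 splits can give, so chance is argued against but not excluded. For the infected lists 6 of 35 gave at least the real 14 (highest other 17), so chance cannot be excluded. For the difference of effects 15 of 100 splits gave at least the real 1168 genes at an unadjusted p under 0.05. The highest other gave 6288, which points to a structure of the samples, and chance cannot be excluded. For infection 1 of 35 splits, the real split, gave as many genes in wild type (real 550, highest other 0) and in atf-4 animals (real 642, highest other 1). With the same limit of 35 splits, chance is argued against in both but not excluded.

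In 3 of 114 groups tested, a single library stood apart by its gap to the nearest other as a share of the range of its group; chance gives about 1 in 20 groups. The vitellogenin level of infected atf-4 replicate 1 was 0.01 against 0.15 to 0.16 in the others (share 0.945). The grl-16 value of infected atf-4 replicate 4 was 32 against 42.5 to 43.7 (0.896). The atf-5 value of infected atf-4 replicate 3 was 3.11 against 0.915 to 1.17 (0.881). Infected mutant libraries held 1 to 3 reads of atf-5 each, 6 in total, so that gap lies at the floor and says nothing about the library.

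The effect of atf-4 differed between infected and uninfected animals for 13 lists by the preset camera on the difference. The median difference, infected less uninfected, was higher for ribosomal proteins (0.42, adjusted p = 1.9e-14), neuropeptides (0.41, 2.1e-05), heat shock proteins (0.37, 1.2e-04), antimicrobial peptides (0.35, 0.0037), oocyte and germline markers (0.23, 0.0037), insulin outputs (0.23, 0.0054), C-type lectins (0.25, 0.016), vitellogenins (0.45, 0.021) and oxidative stress genes (0.16, 0.021). It was lower for F-box, MATH and BTB genes (-0.33, 7.8e-08), embryo markers (-0.63, 1.8e-06), nuclear hormone receptors (-0.18, 3.7e-05) and the intracellular pathogen response (-0.29, 0.028). With an estimated correlation the adjusted p was 0.63 to 0.64 for these lists, and by fry 0 lists passed, so the differences rest on the preset alone.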

How the results depend on the processing

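Chosen only after the data were seen were the fits with 1 surrogate variable, those without a pair of libraries, leaving out each library for list and overlap counts, the block for the overlap, and the list tests on the difference and on infection.

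The replicate block, taken as a pairing in the uninfected comparison, gave 138 genes there and changed no list call, and gave 35 genes in the overlap with the infected comparison left unblocked, and 70 with both blocked. Where the numbers did not pair the samples, the block gave 3003 genes in infected animals and 1289 and 482 for infection in wild type and atf-4. In wild type 675 of these were higher and 614 lower, so the excess of lower genes was not kept with the block. In no comparison, the uninfected one included, did every sample correlate best with its own number. In the infected comparison same-numbered samples correlated at 0.00, 0.09, 0.08 and 0.44. The infected PMK-1 list was lost with the block (adjusted p = 0.084), and muscle markers were gained (0.0048, against 0.056 without it; adjusted p = 0.79 with an estimated correlation and no block).

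For uninfected genes (13) the count was 77 with DESeq2, 39 with all 16 libraries in one fit, 75 with 1 surrogate variable, 8 without atf-4 libraries 3 and 4, and 9 to 44 leaving out 1 library. For infected genes (831) it was 1659 with DESeq2, 27 with all 16 libraries, 77 with a 2-fold threshold, 3067 with 1 surrogate variable, 552 without wild-type libraries 1 and 2 (315 shared with the 831), and 112 to 1206 leaving out 1 library. For the difference (0) DESeq2 gave 3, and leaving out 1 library gave 0 each time, with 531 to 3559 at an unadjusted p under 0.05. For infection DESeq2 gave 952 genes in wild type and 1002 in atf-4, and leaving out 1 library gave 370 to 715 and 358 to 1110. The overlap (10) was 6 at an adjusted threshold of 0.01, and 6 to 20 leaving out 1 library.

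With an estimated correlation 0 lists passed in any comparison. Fry gave 0 lists in uninfected animals, 5 in infected animals, 0 for the difference, and 10 and 5 for infection in wild type and atf-4. Leaving out 1 library gave 4 to 14 uninfected lists and 9 to 16 infected lists. A filter at 50 gave 8 and 10. In uninfected animals it lost the pathogen response, collagens and molting-cycle genes (adjusted p = 0.11, 0.89 and 0.89). The 8 lists there include one higher in the mutant that did not pass in the main fit. In infected animals it lost the PMK-1, F-box, insulin and molting lists (0.090, 0.055, 0.090 and 0.090).

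Some genes selected by the naming rule passed under every alternative in which they were counted, and 0 reversed. They were 3 of 7 in uninfected and 5 of 86 in infected animals. For infection they were 55 of 70 in wild type and 64 of 82 in atf-4. Genes changed less than 2-fold, such as acdh-2 among the 5, were not counted under the 2-fold threshold, which they miss. Other alternatives kept each of the counts past the threshold given above within 1.5 times of its value. The cause of these differences was not tested; fits without a library have fewer samples. Depth limits calls for low genes, and fold changes there are understated.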

Other observations

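The list tests on infection given here were chosen only after the results were seen. In uninfected animals several groups of transcripts varied together between libraries of one genotype. The first principal component held 48.5% of the variance. The mean ribosomal protein level, as a log2 deviation from the gene means, was 0.25, 0.43, -0.26 and -0.16 in wild-type replicates 1 to 4 and 0.38, 0.04, -0.30 and -0.39 in atf-4 replicates 1 to 4. Vitellogenins stood at 0.37, 0.30, -0.04 and -0.24 in wild type and at 0.36, 0.17, -0.41 and -0.52 in atf-4. Embryo markers stood at 0.68 in atf-4 replicate 4 and at -0.42 in wild-type replicate 2, the extremes of this list in the table.

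With infection, ribosomal protein genes had a median log2 fold change of -0.22 in wild type and 0.17 in atf-4 animals, with 0 of 76 past the threshold in each by edgeR, over all genes and adjusted over the list alone. The preset camera gave adjusted p = 1.3e-05 and 8.1e-07, and with an estimated correlation adjusted p = 0.78 and 0.71. Embryo markers in atf-4 animals were lower in 7 of 40 and higher in 2, and 18 and 2 when adjusted over the list alone (camera adjusted p = 1.7e-06; adjusted p = 0.57 with an estimated correlation); hil-3 fell by 0.68 on the log2 scale (lost without infected replicate 1 or 3, adjusted p = 0.054 and 0.051) and sdz-6 rose by 1.40. Genes of the endoplasmic reticulum stress list fell in 4 of 28 in wild type and 5 in atf-4, 5 and 7 when adjusted over the list alone, with pdi-6 and ckb-2 in both (camera adjusted p = 0.0031 and 0.017; with an estimated correlation adjusted p = 0.28 and 0.29). Cytosolic tRNA synthetase genes were positive in 19 of 21 in atf-4 animals, with 0 past the threshold (camera adjusted p = 0.0044; adjusted p = 0.56 with an estimated correlation).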
